A study of Mus musculus with 8 samples.

How the data were processed

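RNA of CD4 T cells sorted from the colonic lamina propria of mice was measured on 8 single-colour Affymetrix arrays. Each array is the only one of its group. The 8 groups cross 4 mouse sources with 2 cell types, regulatory T cells (Treg) and the remaining CD4 T cells (Tconv, called non-Treg in the labels). The sources are specific-pathogen-free (SPF) wild-type IQI mice, germ-free (GF) mice, and SPF C57BL/6 mice that carried either the wild-type (+/+) or the floxed (fl/fl) Uhrf1 gene under Cd4Cre deletion. The strain of the germ-free mice is given only as GF. How many mice stand behind an array is not given in the sources used here. Per the labels, cells were sorted by flow cytometry, RNA was extracted with TRIzol, and biotin-labelled cRNA was prepared from total RNA.

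The deposited values are log2 signals of 45101 probe sets, from -3.56 to 14.73. The authors made these log2 values with MAS5 and affy, per the submitters' processing notes, which give no versions. The order of their steps is not given in the sources used here. All 8 columns hold the same sorted values, with a largest difference of 0.0, so the deposited log2 values had been quantile normalized across arrays. Their median is 5.88, and the trimmed mean of the linear signal is 499.86 with 2% taken off each end. Equal distributions hide any difference in total signal between arrays, and every difference below is relative to the rest of the genes on an array.

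The 64 control probe sets were left out, which left 45037. Of these, 34945 carry 1 gene symbol in the platform annotation, 932 carry several and 9160 carry none. The last 2 kinds were not named or used for genes. Through gene IDs, 34754 probe sets were found in a RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols changed. Each of 18193 genes was represented by its probe set with the highest mean over the 8 arrays. MAS5 signals near background are noisy, so values were raised to a floor of 5.88 (log2), the 50th percentile of the non-control probe sets. The detection level was 7.0, the 60th percentile. A fold against an array at the floor is a lower bound and is written as at least N-fold, also for a mean over sources in which any dimmer array lies at the floor. A log2 difference of such a gene is a bound in the same way. A fold of a gene near the floor is understated. In a comparison of 1 array with 1, a gene at the floor on 1 array is measured only through the other, which fixes its direction.

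Treg and Tconv were compared with limma 3.58.1 in R 4.3.3, with lmFit, the mouse source as a covariate, and eBayes with an intensity trend. The 9656 genes above the detection level on at least 3 arrays were tested, two-sided, with Benjamini-Hochberg adjustment at 0.05. The replicate is the mouse source, 4 arrays per cell type, so the error is how the cell type difference varies between sources that also differ in microbiota, strain and genotype. Of 33 gene lists for cell types and programs, the 26 with at least 5 tested genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The comparisons between mouse sources set 1 array against 1 array. They have no replicate check and no p-value. Whether such a difference itself differed between Treg and Tconv was tested with limma and the same gene list tests by adding a contrast of cell type with the source pair, which leaves 2 residual degrees of freedom and counts all other differences between sources as error. This test was chosen after the data were seen. In the comparisons of 1 array with 1 a gene was measured when at least 1 of the arrays reached the detection level, and it was counted as different when the arrays were at least 2-fold apart after the floor with the brighter array above the detection level. A list's median difference was set against 10000 random lists of the same size matched on mean expression, as a description of those arrays. The number of arrays limits the precision throughout.

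Groups, comparisons and their main tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The fits on 4 arrays alone and the counts without certain genes were added later, as were all but 1 of the tests of explanations. For Treg against Tconv the rule takes the 10 largest rises and 10 largest falls among genes past the threshold that moved the same way in all 4 sources. For each comparison of 1 array with 1 it takes the 6 largest differences each way among genes whose other probe sets above the detection level differ in the same direction, leaving out unnamed, predicted and sex-linked genes. For the germ-free and the Uhrf1 comparisons it adds the 5 largest each way over both cell types. Uhrf1, Foxp3, Cdkn1a, Il10 and Ctla4 are always given, with up to 4 members of each described list. A list is described where at least 3 members differ or its median lies outside the central 95% of random lists. Lists share members: Il10, for example, stands in the Treg, effector, Th2 and IL-2 lists. Some well-known T cell genes are not analysed here because no single-gene probe set carried their symbol in the annotation used.

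The limma step was tested on simulated data of the same 9656 genes. It called 61 of 100 genes changed by 1 log2 unit, 84 of 100 changed by 2, and 7 unchanged genes. Residual spreads were drawn at random across genes, and the noise was normal, independent between genes and without a floor. These counts therefore do not give the rates for dim or correlated genes. The random-list step was tested on the 8986 genes of the Uhrf1 comparison in Tconv. It placed 100 of 100 lists of 20 genes shifted by 0.5 log2 units outside the central 95%, and 5 of 100 unshifted lists. The alternatives were another floor, a pseudocount in place of the floor, a second quantile normalization, centring on detected genes, the median of all probe sets of a gene, no _x_at and _s_at probe sets, other fold thresholds, other limma settings, and leaving out each mouse source in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the rest. No genome sequence was used, and no coordinates are given.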

Results

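Gene expression was measured in Treg and Tconv cells of the colonic lamina propria from 4 mouse sources, SPF IQI, GF, Uhrf1 +/+ and Uhrf1 fl/fl, with 1 array per group and 8 in all. Between 8754 and 9375 genes were above the detection level on each array. The 4 SPF IQI and GF arrays stood apart from the 4 Uhrf1 arrays in their control probe sets. The bacterial BioB spike-in read 10.66 to 12.48 (log2) on the former and 6.84 to 7.05 on the latter, a mean difference of 4.35. The 3' probe set of beta-actin was 1.91 to 2.46 times its 5' probe set on the former and 1.43 to 1.56 times on the latter, and for GAPDH the ratios were 1.53 to 1.83 and 1.42 to 1.53. Among SPF IQI and GF arrays, BioB was highest on the GF Treg array, at 12.48, against 10.67 on the SPF IQI Treg array. Over genes, which are not independent replicates, the Spearman correlation was 0.979 between the Uhrf1 +/+ and fl/fl Tconv arrays and 0.967 between the Treg arrays. It was 0.948 between SPF IQI and GF Treg, 0.941 between SPF IQI and GF Tconv, and 0.817 between the SPF IQI and Uhrf1 +/+ Treg arrays. Across cell types it was 0.9505 between SPF IQI Tconv and GF Treg and 0.8822 between SPF IQI Treg and GF Tconv.

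**Figure D1:**
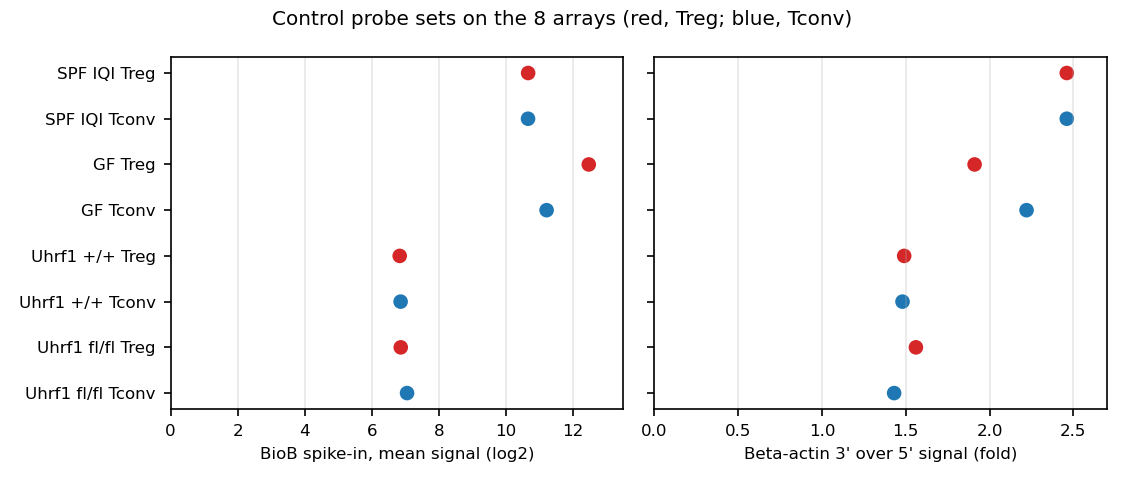
Mean log2 signal of the BioB spike-in (left) and the ratio of beta-actin 3' to 5' signal in fold (right) on each of the 8 arrays, 1 point per array, red for Treg and blue for Tconv. The SPF IQI and GF arrays lie at 10.66 to 12.48 for BioB and the Uhrf1 arrays at 6.84 to 7.05.

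The first comparison asks which transcripts separate colonic Treg from Tconv cells across all mouse sources. Foxp3, the transcription factor that defines Treg cells, was 33.0-fold higher in Treg (log2 difference 5.04, SD 0.67 over 4 sources, limma adjusted p = 0.000132). Klrg1, an inhibitory receptor of differentiated T cells, was at least 21.1-fold higher. Il2ra, the alpha chain of the IL-2 receptor, was at least 20.9-fold higher and Itgae, the alpha E integrin chain, at least 18.5-fold higher. Ebi3, a subunit of IL-35 and IL-27, rose at least 15.5-fold, the cytotoxic protease Gzmb at least 13.8-fold, the suppressive mediator Fgl2 at least 13.7-fold and Itgb8, an integrin chain that activates TGF-beta, at least 11.5-fold. Sdc4 rose 11.4-fold and Cd79b, a component of the B cell receptor, 11.7-fold. In the other direction Pdlim4 fell most in Treg (log2 difference -3.81, SD 0.97 over 4 sources, limma adjusted p = 0.000559). Lypd6b was at least 6.87-fold lower, Dntt, the terminal transferase of antigen receptor rearrangement, at least 6.64-fold lower and Ampd1 at least 5.94-fold lower. Vwce, Ggt5, Xkrx, Hs3st3b1, Il1rl2 and Tdrp fell by log2 differences of -2.29, -2.28, -2.27, -2.17, -2.11 and -2.09, with Vwce, Ggt5 and Xkrx at the floor on some Treg arrays. All 20 of these genes differed in the same direction in the 4 sources, which the rule that picked them required.

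**Figure D2:**
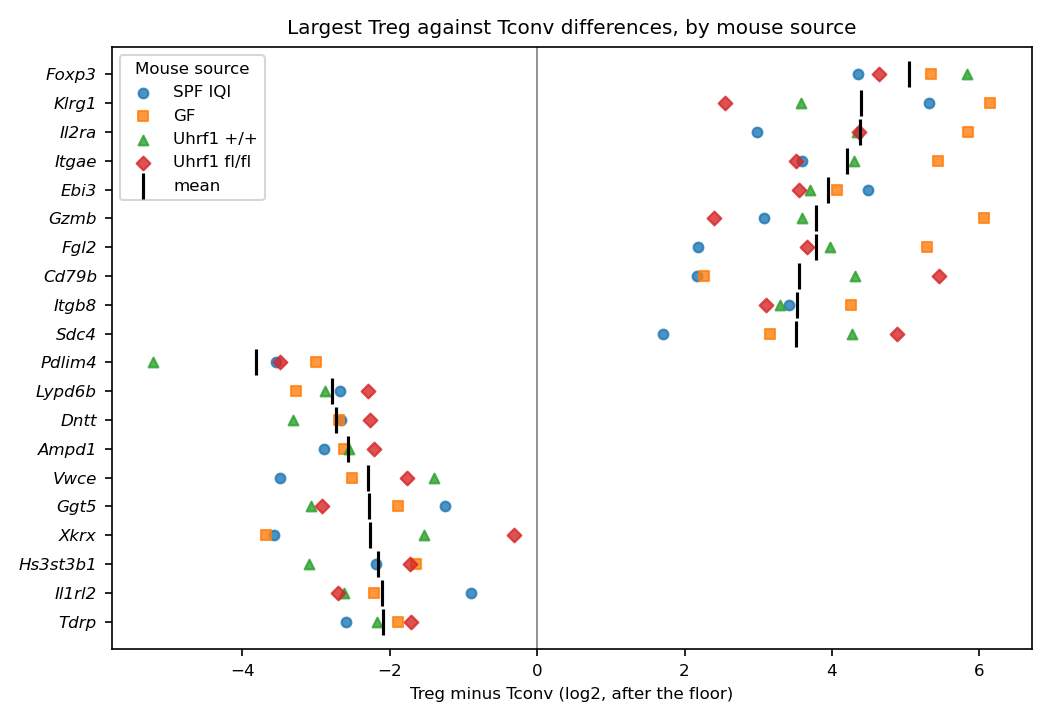
Treg minus Tconv log2 difference after the floor for the 10 largest rises and 10 largest falls past the threshold, with 1 symbol per mouse source and a bar at the mean. Foxp3 lies at a mean of 5.04 and Pdlim4 at -3.81. Each gene lies on 1 side of 0 in all 4 sources, which the rule that picked them required.

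In all, 903 of 9656 genes differed between Treg and Tconv, 613 higher and 290 lower in Treg, and 898 of the 903 differed the same way in every source. Uhrf1, an adaptor that recruits the maintenance DNA methyltransferase to replicating DNA, was 1.82-fold higher in Treg (log2 difference 0.86, SD 0.29 over 4 sources, limma adjusted p = 0.0111). Cdkn1a, which encodes a cyclin-dependent kinase inhibitor, rose 2.5-fold, the inhibitory receptor gene Ctla4 4.45-fold and Il10 at least 9.23-fold. Il10 lay at the floor on 3 of 4 Tconv arrays and below the detection level on both Uhrf1 fl/fl arrays, so the floor sets part of its SD of 2.57 log2 units over sources.

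All 24 genes of the Treg signature list rose, also when adjusted over the list alone, with a median log2 difference of 2.61 (camera adjusted p = 3.91e-29; adjusted p = 0.326 with an estimated correlation). Of 14 effector and suppressor molecules of mature Treg cells, 13 rose, and 13 when adjusted over the list alone (camera adjusted p = 1.6e-13, and adjusted p = 0.326 with an estimated correlation). Of 13 genes of naive and resting T cells, 9 fell, and 12 fell when adjusted over the list alone (camera adjusted p = 4.8e-10, and adjusted p = 0.331 with an estimated correlation). Among them Dapl1, Pde3b, Igfbp4 and S1pr1, the receptor that guides T cells out of tissue, fell by -1.98, -1.47, -1.32 and -1.16 on the log2 scale.

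Part of the T helper genes rose in Treg. Of 10 Th1 genes 3 rose, Il18rap by 1.97, the chemokine receptor Cxcr3 by 1.47 and the lineage factor Tbx21 by 1.24 log2 units, and 6 when adjusted over the list alone (camera adjusted p = 0.0141, and adjusted p = 0.544 with an estimated correlation). All 5 Th2 genes rose, also when adjusted over the list alone, among them Ccr8 by 2.73, Il17rb by 1.73 and Il4 by 1.39 (camera adjusted p = 0.000164, and adjusted p = 0.429 with an estimated correlation). Il10 and Ccr8 also stand in the Treg signature list. Of 10 Th17 genes 4 rose, Ccr6 by 2.30, the aryl hydrocarbon receptor Ahr by 1.92, Rora by 1.08 and Irf4 by 0.72, and 5 when adjusted over the list alone (camera adjusted p = 0.00269, and adjusted p = 0.458 with an estimated correlation). Among 9 follicular helper genes Pdcd1 rose by 2.28, Icos by 0.62 and Cd40lg fell by -1.11 (camera adjusted p = 0.0568, and adjusted p = 0.429 with an estimated correlation).

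Part of the proliferation genes rose in Treg. Of 17 G2 and M phase genes 3 rose, Mki67, the antigen of cycling cells, by 1.81, Ube2c by 1.0 and Top2a by 0.96, and 13 when adjusted over the list alone (camera adjusted p = 1.41e-06, and adjusted p = 0.452 with an estimated correlation). The median of the list was 0.90 in SPF IQI, 0.00 in GF, 1.0 in Uhrf1 +/+ and 1.61 in Uhrf1 fl/fl. The list's median level was 5.88, the floor, on GF Treg and 6.01 on GF Tconv, so the floor hides differences in GF. Of 26 G1 and S phase genes 5 rose, among them the thymidine kinase Tk1 by 1.65, Cdk6 by 1.04 and the replicative helicase subunit Mcm5 by 0.88, and 6 when adjusted over the list alone (camera adjusted p = 0.0034, and adjusted p = 0.544 with an estimated correlation). Of 17 IL-2 and STAT5 response genes 9 rose, with the signalling inhibitor Socs2 11.3-fold higher, and 9 when adjusted over the list alone (camera adjusted p = 0.000123, and adjusted p = 0.429 with an estimated correlation). Il2ra, Il2rb, Socs2 and Il10 of this list also belong to the Treg signature. Of 16 glycolysis genes 4 rose, Hk2 by 1.56, the lactate transporter Slc16a3 by 1.19, Tpi1 by 1.04 and Slc2a3 by 0.45, and 6 when adjusted over the list alone (camera adjusted p = 0.000186, and adjusted p = 0.331 with an estimated correlation). Of 13 gut homing and residency genes 4 rose, among them the colon homing receptor Gpr15 by 2.96 and Ccr9 by 1.84, and 1, S1pr1, fell (camera adjusted p = 0.0273, and adjusted p = 0.544 with an estimated correlation).

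Markers of other cell types differed between the sorted fractions too. Of 8 B cell genes 3 rose, among them Cd79a by 2.75 and Blk by 2.34, and 7 when adjusted over the list alone (camera adjusted p = 4.02e-05, and adjusted p = 0.452 with an estimated correlation). The median Treg minus Tconv difference of the B cell list was 0.38 in SPF IQI, 1.49 in GF, 3.48 in Uhrf1 +/+ and 5.24 in Uhrf1 fl/fl. Of 10 macrophage and dendritic cell genes 4 rose, H2-Eb1 by 2.89, Cybb by 2.12, H2-Ab1 by 2.12 in 3 of 4 sources and Cd74 by 1.73, and 6 when adjusted over the list alone (camera adjusted p = 0.000269, and adjusted p = 0.458 with an estimated correlation). The median of the macrophage and dendritic cell list was -0.11 in SPF IQI, 1.24 in GF, 1.88 in Uhrf1 +/+ and 2.57 in Uhrf1 fl/fl. This is the same order as for the B cell list, so a separate difference in macrophages is not told apart here. Single members of other lists passed the threshold without a call of the list. Among these, the demethylase Tet1 fell by -1.90, Gadd45b rose by 1.0, the interferon-induced Gbp3 rose by 2.41 and Oas2 fell by -1.15. The lists for the interferon response, DNA methylation machinery, imprinted genes, immediate early genes, apoptosis, the p53 response, cholesterol synthesis, protein folding, pan T cell genes, epithelium, stroma, and CD8 T and NK cells had camera adjusted p from 0.0799 to 0.709.

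With an estimated correlation 0 of the 26 lists passed, against 13 with the preset one, and fry, which asks whether a list's genes move one way without comparing them with other genes, gave adjusted p = 0.0274 for the Treg signature, 0.0276 for the effector molecules and 0.038 for glycolysis. The other 10 lists called by camera had adjusted p from 0.0595 to 0.285 by fry. The count of genes fell to 577 with the median of all probe sets, 518 without the intensity trend, 39 without the mouse source term, 276 without Uhrf1 +/+ mice and 489 without Uhrf1 fl/fl mice, and limma called 0 genes on the SPF IQI and GF arrays alone (1095 at an unadjusted p under 0.05) and 0 on the Uhrf1 arrays alone (1691).

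The next comparison asks how colonic T cells of germ-free mice differ from those of SPF mice. On the GF Treg array Uhrf1 was 2.58-fold lower than on the SPF IQI Treg array, a log2 difference of -1.37. With the median of both its probe sets the difference became -2.75. The other probe set read 6.17 on SPF IQI Treg and 0.85 on GF Treg, so that value rests on dim signal and the floor. Mitotic genes were lower as a group. Of 16 measured G2 and M phase genes 11 were lower and 0 higher, with a median of -1.52, below the central 95% of random lists (-0.74 to 0.25). Birc5, an inhibitor of apoptosis with a role in mitosis, was 8.55-fold lower, cyclin gene Ccna2 at least 7.20-fold, Nusap1 5.79-fold and Ccnb2 at least 4.56-fold lower. Of 26 G1 and S phase genes 5 were lower, with a median of -0.49 (random lists -0.36 to 0.15), among them Tk1 6.28-fold, the replication licensing factor Cdc6 3.56-fold and the DNA polymerase gene Pola1 2.75-fold. Differences in this comparison come from 1 array per group and have no replicate check.

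Of 9725 genes measured in Treg, 374 were higher and 994 lower in GF. Calr3 was at least 32.5-fold higher, the gut hormone gene Pyy at least 10.9-fold, Ryr2 9.74-fold, the B cell gene Fcrla at least 9.13-fold, Synpo2l at least 8.27-fold and the immunoglobulin segment Ighv14-2 6.41-fold higher. The epithelial regenerating-islet genes, which encode secreted lectins, were lower, Reg2 at least 120-fold, Reg3b 76.3-fold, Reg3a at least 25.5-fold and Reg3g 21.4-fold. Nebl was 24.9-fold and Pcolce, a collagen-processing factor, 14.9-fold lower.

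The Treg signature itself differed little in Treg cells. None of its 24 measured genes was 2-fold apart, and its median of -0.13 lay inside the range of random lists (-0.21 to 0.15), with log2 differences of -0.44 for Foxp3 and -0.13 for Ctla4. Il10 differed by -0.56 and Cdkn1a by -0.61. Effector molecules of mature Treg cells had a median of -0.55 (random lists -0.30 to 0.20), with Lag3 2.64-fold and the transcription factor gene Prdm1 2.22-fold lower as the 2 members that differed among 15. Genes of naive and resting T cells were higher, 5 of 13 with a median of 0.63 (random lists -0.29 to 0.22). Dapl1 was 3.08-fold, S1pr1 2.71-fold, its regulator Klf2 2.59-fold and the survival gene Bcl2 2.55-fold higher.

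Part of the Th1, Th17 and Th2 genes was lower in GF Treg. Of 10 Th1 genes 5 were lower, with a median of -1.06 (random lists -0.47 to 0.29), the chemokines Ccl3 3.87-fold, Ccl5 3.34-fold and Ccl4 at least 2.44-fold, and Ifng 2.68-fold. Of 10 Th17 genes 5 were lower, with a median of -1.01 (random lists -0.47 to 0.27), Il1r1 11.3-fold, Il17a 5.19-fold, Il21 at least 3.98-fold and Tmem176a 2.24-fold. Of 8 Th2 genes 3 were lower, with a median of -0.89 (random lists -0.59 to 0.33), Ccr4 6.29-fold, Il5 4.33-fold and Il4 2.55-fold. Of 8 follicular helper genes 2 were lower, and their median of 0.14 lay inside the range of random lists (-0.41 to 0.28). Gut homing and residency genes had a median of -0.64 (random lists -0.29 to 0.22), with Ccr9 4.61-fold and Gpr15 2.32-fold lower and S1pr1 and Klf2 higher. Glycolysis genes had a median of -0.34 (random lists -0.30 to 0.20), with Hk2 2.29-fold and Aldoc 2.03-fold lower. IL-2 and STAT5 response genes had a median of -0.28 (random lists -0.27 to 0.19), with Bcl2 as the 1 member that differed. Of 17 genes of the DNA methylation machinery 3 were lower, Uhrf1, the repair glycosylase Mbd4 3.8-fold and the methyltransferase gene Dnmt3b 2.01-fold, and the median of -0.26 lay inside the range of random lists (-0.33 to 0.20). Among 7 imprinted genes Mest was 2.55-fold and Grb10 2.27-fold lower and Kcnq1ot1 2.40-fold higher, and with the median of all probe sets Grb10 differed by 0.03.

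Interferon-induced genes were higher in GF Treg, 11 of 25 with a median of 0.89 (random lists -0.35 to 0.18). The antiviral genes Oas2, Mx1, Usp18 and Oasl2 were 5.51-fold, 4.59-fold, 3.95-fold and 3.54-fold higher. B cell markers were higher as well, 5 of 8 with a median of 1.49 (random lists -0.79 to 0.40), Ms4a1 6.13-fold, Cd79a 5.86-fold, Blnk 3.26-fold and Cd22 3.01-fold. Of 11 stromal and endothelial genes 7 were lower and 2 higher, with a median of -1.89 (random lists -0.58 to 0.32), the collagens Col1a2 8.64-fold, Col1a1 5.99-fold and Col3a1 5.04-fold and the proteoglycan Lum at least 6.18-fold lower. Of 11 macrophage and dendritic cell genes 5 were lower and 3 higher, with Csf1r at least 4.62-fold, C1qb 3.42-fold, Fcgr3 at least 3.21-fold and Cd68 2.5-fold lower and H2-Ab1, H2-Eb1 and H2-Aa higher by 1.21, 1.19 and 1.13 log2 units. The median of this list, -0.58, lay inside the range of random lists (-0.67 to 0.32) and became 0.87 with the higher floor and 0.12 with the median of all probe sets. The epithelial list had a median of 0.34 (random lists -0.44 to 0.23), with the goblet cell genes Spink4 2.84-fold and Muc2 2.04-fold lower and Krt19 2.31-fold higher. Of 4 genes of tissues outside the gut, Ttr was at least 4.84-fold higher. Xist, transcribed from the inactive X chromosome of females, was 49.0-fold lower on the GF array, while the Y-linked Eif2s3y differed by 0.77 log2 units, and the median of the 4 sex-linked genes was 0.59. The GF Treg and Tconv arrays held Y-linked transcripts with Xist below the detection level, at 6.14 and 6.34. The SPF IQI arrays held both, with Xist at 11.76 and 11.95. The sex of the mice thus appears to differ between GF and SPF IQI as well as the microbiota, and this comparison cannot tell them apart. With the median of all probe sets Eif2s3y and the sex-linked list each differed by -0.64.

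Of 9522 genes measured in Tconv, 277 were higher and 904 lower in GF. The higher ones were fewer with a pseudocount, 110 against 743 lower, and with the floor at the 60th percentile, 120 against 581. With the median of all probe sets they were 316 against 597, and at 1.5-fold 1018 against 1293. Here Treg and effector genes were lower, 16 of 22 Treg signature genes with a median of -1.44 (random lists -0.18 to 0.30). Il2ra was at least 10.9-fold, Socs2 8.49-fold, Il10 at least 8.02-fold, Itgae at least 5.60-fold, Ctla4 3.53-fold and Foxp3 2.68-fold lower. In SPF IQI mice the Treg minus Tconv difference was 4.36 for Foxp3, 2.98 for Il2ra and 0.74 for Ctla4. Of 12 effector molecules 8 were lower, with a median of -1.31 (random lists -0.27 to 0.34), among them Gzmb 15.5-fold and Fgl2 at least 9.27-fold. Uhrf1 differed by -0.90 and Cdkn1a by -0.51 log2 units. With the median of both Uhrf1 probe sets, the other of which lies near or below the floor, Uhrf1 differed by 0.26.

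Most Th1, Th17 and Th2 genes were lower in GF Tconv. Of 9 Th1 genes 7 were lower, with a median of -2.0 (random lists -0.39 to 0.43), Ccl3 at least 12.6-fold, Il18rap at least 8.13-fold, the residency receptor Cxcr6 7.63-fold and Ifng 7.47-fold. Of 10 Th17 genes 9 were lower, with a median of -2.11 (random lists -0.32 to 0.36), Il1r1 at least 27.9-fold, Tmem176b 6.68-fold, Il17a at least 5.75-fold and Tmem176a 5.67-fold. Of 4 Th2 genes 3 were lower, with a median of -1.28 inside the range of random lists (-1.41 to 0.77), Il10, Il4 at least 2.64-fold and Il17rb 2.23-fold. Of 8 follicular helper genes 2 were lower, with a median of -0.49 (random lists -0.22 to 0.29), Tox2 12.2-fold and Il21 at least 4.0-fold. Of 17 IL-2 and STAT5 response genes 9 were lower, with a median of -1.03 (random lists -0.13 to 0.27). Of 13 homing and residency genes 6 were lower, among them Itga1 7.46-fold and Gpr15 at least 6.99-fold.

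Of 12 G2 and M phase genes 5 were lower in GF Tconv, with a median of -0.73 (random lists -0.65 to 0.49), Mki67 5.32-fold, Ccna2 at least 2.99-fold, Birc5 2.86-fold and Tpx2 at least 2.33-fold. None of 23 G1 and S phase genes differed. Interferon-induced genes were again higher, 12 of 25 with 1 lower and a median of 0.93 (random lists -0.11 to 0.27), among them Oasl2 4.01-fold, Oas3 3.57-fold, Ifit1 3.48-fold and Ifit3 3.3-fold. None of 15 cholesterol synthesis genes was 2-fold apart, yet their median of 0.45 lay above the random lists (-0.13 to 0.24), with log2 differences of 0.91 for the squalene epoxidase Sqle and 0.86 for Msmo1. Naive T cell genes had a median of 0.17 (random lists -0.11 to 0.15) with 0 of 13 members 2-fold apart. Of 22 immediate early genes 4 were lower, with a median of -0.20 (random lists -0.08 to 0.15), among them Ier3 7.48-fold and Atf3 3.89-fold. Of 16 apoptosis genes Bcl2l1 was 2.31-fold and Bad 2.12-fold lower and Bmf 2.08-fold and Bbc3 at least 2.22-fold higher, and of 9 imprinted genes Grb10 was 10.2-fold, Plagl1 3.32-fold and Peg3 at least 2.21-fold lower and Meg3 at least 2.71-fold higher.

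Stromal genes were lower in GF Tconv, 10 of 11 with a median of -2.87 (random lists -0.30 to 0.35), the proteoglycan Dcn 20.9-fold and Col1a2 13.6-fold. Epithelial genes were lower for 7 of 17, with a median of -0.81 (random lists -0.17 to 0.32), macrophage and dendritic cell genes for 4 of 9, with a median of -0.92 (random lists -0.45 to 0.44), and CD8 T, NK and innate lymphoid genes for 4 of 6, with Klrk1 5.04-fold lower. Plasma cell genes had a median of -0.63 (random lists -0.44 to 0.35), with the surface marker Sdc1 2.34-fold lower, and the B cell list had a median of 0.55 (random lists -0.82 to 0.59). The genes with the largest differences were an immunoglobulin kappa variable segment, at least 22.8-fold higher, Cps1, at least 5.44-fold, the proglucagon gene Gcg, at least 5.14-fold, Zfp658 4.54-fold, Tarbp2 4.36-fold and Cd79a 4.05-fold. Reg2 was at least 79.2-fold lower, Reg3b 56.5-fold, Il1r1 at least 27.9-fold, Reg3g at least 26.8-fold, Tnfaip6 at least 26.1-fold and Htra1 at least 24.8-fold.

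Between the cell types, 43 genes were higher in GF in both, where independent lists would share 5.7, and 366 were lower in both, where they would share 71.1. Calr3, Ryr2, Pyy, Fcrla and Cd79a led the shared rises, and Reg2, Reg3b, Reg3g, Reg3a and Il1r1 the shared falls. The difference between Treg and Tconv in the GF effect had a median of 1.25 for the Treg signature, 1.22 for Th17, -0.84 for G2 and M phase and 0.18 for interferon genes, over the genes tested in limma. Tested in limma against the other differences between sources, with 2 residual degrees of freedom, this difference passed the threshold for 0 genes (lowest adjusted p = 0.415). By camera these lists had adjusted p = 2.41e-08, 9.03e-05, 0.0271 and 0.163, and with an estimated correlation adjusted p = 0.254, 0.254, 0.664 and 0.748. With the floor at the 60th percentile the number of genes apart was 807 in Treg, 701 in Tconv and 241 in both, and Foxp3 in Tconv then differed by -0.61, short of 2-fold. Pan T cell, protein folding and p53 response genes had medians inside the range of random lists in both cell types and fewer than 3 members apart, and the granulocyte, mast cell, erythroid and germline lists had at most 2 measured genes.

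**Figure D3:**
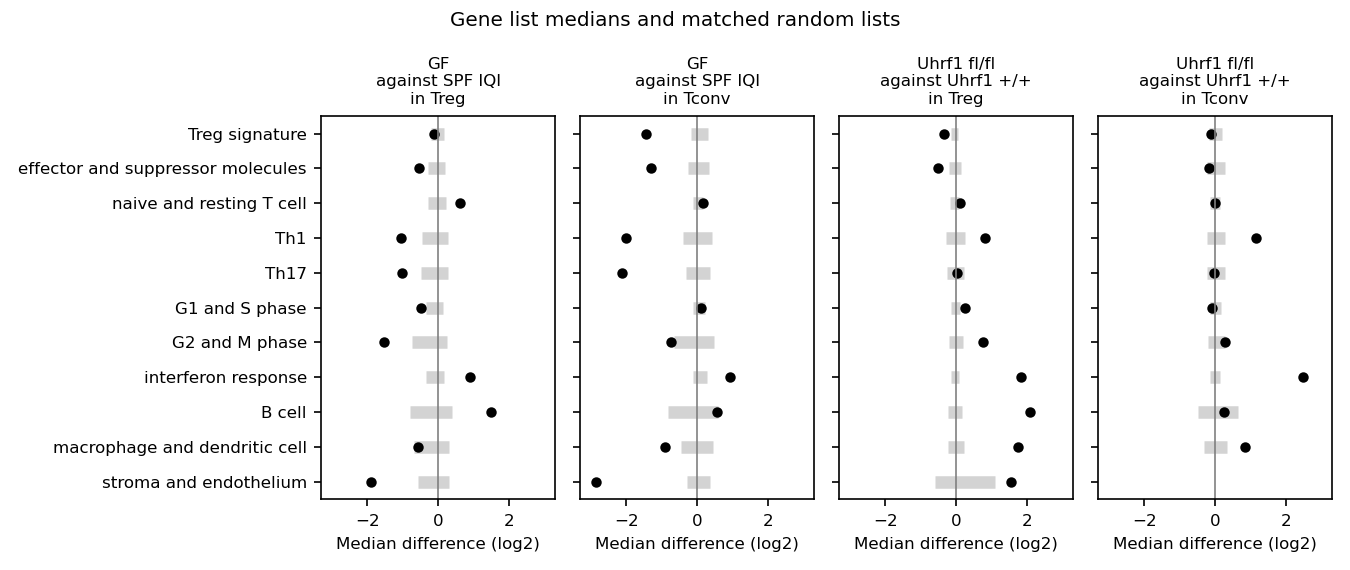
Median log2 difference of 11 gene lists (points) and the central 95% of 10000 random lists of the same size matched on mean expression (grey bars), for GF against SPF IQI and Uhrf1 fl/fl against +/+ in Treg and Tconv, 1 array against 1 array each. The interferon list lies to the right of its bar in all 4 panels, at 0.89, 0.93, 1.82 and 2.49.

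The Uhrf1 comparison asks which transcripts of colonic T cells differ when the Uhrf1 gene is floxed and Cd4Cre is present. Uhrf1 itself read 10.46 on the array labelled Uhrf1 fl/fl Treg and 10.64 on the Uhrf1 +/+ Treg array, 1.13-fold lower. In Tconv it read 9.29 and 9.80, 1.42-fold lower. With the median of both Uhrf1 probe sets the Treg difference of -0.18 became 0.02. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here, and a probe set outside it checks nothing about the deletion. Of 9520 genes measured in Treg, 474 were higher and 116 lower on the fl/fl array, and of 8986 measured in Tconv, 190 were higher and 59 lower. At 1.5-fold 868 were higher and 508 lower in Treg, and 504 and 353 in Tconv. At 3-fold 229 were higher and 14 lower in Treg, and 72 and 7 in Tconv. Each comparison is of 1 array with 1 and has no replicate check.

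Interferon-induced genes were higher on both fl/fl arrays. In Treg 20 of 25 were higher, with a median of 1.82 (random lists -0.16 to 0.09), and in Tconv 22 of 25, with a median of 2.49 (random lists -0.14 to 0.15). Mx1, an antiviral GTPase gene, was 18.7-fold higher in Treg and 21.4-fold in Tconv, Rsad2 17.3-fold and 27.1-fold, Oas2 15.2-fold and 15.8-fold, and Ifit3 11.8-fold and 15.8-fold. The interferon-inducible Slfn4, outside the list, was at least 58.7-fold higher in Treg and at least 24.6-fold in Tconv, and Oasl2 was 12.6-fold higher in Tconv. The same 2 arrays also had higher Th1 genes, 3 of 9 in Treg with a median of 0.80 (random lists -0.28 to 0.26) and 6 of 11 in Tconv with a median of 1.16 (random lists -0.24 to 0.28). Ifng was 2.74-fold higher in Treg and 5.33-fold in Tconv, and Ccl5 3.24-fold and 4.18-fold. Eomes was 2.29-fold higher in Treg, and Il18rap was 2.71-fold and Ccl4 at least 2.62-fold higher in Tconv. CD8 T and NK cells express these genes too, and Cd8a was higher on both fl/fl arrays, at 11.96 against 10.31 in Treg and 9.55 against 7.97 in Tconv.

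Il10 was 6.63-fold lower in fl/fl Treg, at 5.91 against 8.64. The lower reading lies below the detection level and next to the floor of 5.88, and the log2 difference of -2.73 became -1.64 with the higher floor and -1.94 with a pseudocount. Il10 was below the detection level on both Tconv arrays, as was Foxp3. Foxp3 differed by -0.67 and Ctla4 by -0.23 in Treg. Among 24 Treg signature genes Il10, Ccr8 (2.32-fold) and the ectonucleotidase gene Entpd1 (2.02-fold) were lower and Swap70 2.65-fold higher, with a list median of -0.35 (random lists -0.13 to 0.06). Of 14 effector molecules 4 were lower, with a median of -0.52 (random lists -0.19 to 0.13), among them Lag3 3.94-fold and Pdcd1 2.02-fold. Of 5 Th2 genes Il10 and Ccr8 were lower, with a median of -0.84 (random lists -0.46 to 0.69). Follicular helper genes had a median of -0.30 (random lists -0.22 to 0.17), with Pdcd1 as the 1 member that differed. IL-2 and STAT5 response genes had a median of -0.19 (random lists -0.18 to 0.11), with Il10 as the 1 member that differed. Naive T cell genes had a median of 0.11 (random lists -0.16 to 0.09), with Dapl1 4.42-fold and Pde3b 3.18-fold higher, and the median was -0.07 with the median of all probe sets of each gene.

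Mitotic genes were higher in fl/fl Treg. Of 24 G2 and M phase genes 9 were higher and 0 lower, with a median of 0.74 (random lists -0.20 to 0.19), the kinesin genes Cenpe 3.06-fold and Kif11 2.49-fold, the kinase gene Aurkb 2.63-fold and Hmmr 2.57-fold. Of 27 G1 and S phase genes 1, Cdc6, was 2.11-fold higher, and the median was 0.26 (random lists -0.15 to 0.10). Cdkn1a was 2.36-fold higher in Treg and 2.23-fold in Tconv. Its difference fell short of 2-fold in Treg with the median of all probe sets (0.89) and in Tconv with the higher floor (0.93) and with a pseudocount (0.85). The CDK inhibitor and p53 target list, of which Cdkn1a was the only one of 11 members apart in Treg, had a median of 0.31 there (random lists -0.22 to 0.20). In Tconv 0 of 14 G2 and M phase genes and 0 of 22 G1 and S phase genes differed, with medians of 0.27 (random lists -0.20 to 0.29) and -0.09 (random lists -0.14 to 0.16).

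The list of methylation-silenced germline genes holds 24 genes on the array, of which 4 were measured in Treg and were higher. The meiotic Syce1 was at least 5.73-fold, the homeobox gene Rhox5 at least 4.51-fold, the piRNA pathway gene Piwil2 3.19-fold and Tex13b at least 2.32-fold higher. Their median was 1.92 (random lists -0.60 to 1.12). Piwil2 was not silent in other wild-type Treg cells, at 10.02 on the SPF IQI Treg array against 8.72 on the fl/fl Treg array. Syce1, Rhox5 and Tex13b lie at the floor on the +/+ array and count as measured only because the fl/fl array is brighter, which fixes their direction. They are 3 of 22 germline genes at the floor on the +/+ array, and of all 7860 genes at the floor there 101 (1.28%) were above the detection level on the fl/fl array. In Tconv 1 of 3 was higher and the median was 0.58 (random lists -0.53 to 0.86). Protein folding genes had a median of 0.16 in Treg (random lists -0.16 to 0.09), with Hspa1b 2.21-fold higher, and glycolysis genes a median of -0.26 (random lists -0.17 to 0.13) with 0 of 16 apart. DNA methylation machinery and imprinted genes had medians of 0.05 and -0.05 in Treg and -0.06 and 0.01 in Tconv, inside the range of random lists. So did pan T cell, Th17, homing, apoptosis and cholesterol synthesis genes in both cell types, with fewer than 3 members apart in each.

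Markers of other cell types were higher on the fl/fl Treg array. Of 10 B cell genes 8 were higher, with a median of 2.09 (random lists -0.22 to 0.17), Cr2 7.5-fold and Blnk 7.04-fold. Of 4 plasma cell genes 3 were higher, with Igha 10.5-fold and Jchain 8.77-fold. Of 11 macrophage and dendritic cell genes 7 were higher, with a median of 1.75 (random lists -0.24 to 0.22), H2-Aa 4.48-fold and Csf1r 4.30-fold. The 3 measured granulocyte genes, S100a9 at least 16.8-fold, and 3 of 4 stromal genes, Col1a1 at least 6.32-fold, were higher too, but all 6 lie at the floor on the +/+ array, and being measured only through the fl/fl array fixes their direction. Of 8 CD8 T, NK and innate lymphoid genes 7 were higher, with a median of 2.37 (random lists -0.28 to 0.33), among them the NK receptor gene Klrd1 20.5-fold and Fcer1g 8.16-fold. In Tconv the B cell list had a median of 0.26 (random lists -0.48 to 0.64) with 0 of 3 genes apart, the macrophage and dendritic cell list a median of 0.85 (random lists -0.30 to 0.34) with H2-Ab1 2.79-fold and Cd74 2.31-fold higher, and the CD8 T and NK list a median of 0.31 (random lists -0.30 to 0.38) with 2 of 5 genes higher. These were Cd8a, at 9.55 against 7.97, and Cd8b1, at 9.44 against 8.31.

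The other genes named by size were Clvs1, at least 18.8-fold higher in fl/fl Treg, and, lower there, the interferon-induced Gbp2b 9.25-fold, Sccpdh 7.73-fold, Hoxb3 5.91-fold, Ryr2 at least 4.35-fold and Gprin3 4.10-fold. In Tconv Glycam1, a ligand of L-selectin on high endothelial venules, was at least 16.1-fold lower, the follicle chemokine Cxcl13 at least 4.17-fold, Fbn2 at least 3.79-fold, Igk-V21 at least 3.69-fold, H2-Ob 3.22-fold and Fam199x 3.15-fold. Among 10 effector molecules in Tconv Gzmb was at least 3.91-fold and Klrg1 at least 2.73-fold higher and Cd44 2.10-fold lower. Klrg1 was also higher among 18 Treg signature genes, of which Tnfrsf9 was 2.26-fold and Cd83 2.23-fold lower. Of 20 immediate early genes in Tconv Ier3 was at least 2.89-fold and Jun 2.02-fold higher and Egr3 2.39-fold lower.

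In both cell types 110 genes were higher on the fl/fl arrays, where independent lists would share 4.8, and 9 were lower, where they would share 0.3. Ttc28, Dhrs3, Sostdc1, Gpm6b and Tlcd5 led the shared falls, at 3.48-fold, 3.02-fold, 2.48-fold, 2.37-fold and 2.48-fold in Treg. The fl/fl effect in Treg minus that in Tconv had a median over the genes tested in limma of 1.96 for B cell genes, 0.51 for G2 and M phase, 0.44 for G1 and S phase and -0.28 for interferon genes. The same limma test of this difference called 0 genes (lowest adjusted p = 0.113), and camera gave adjusted p = 0.00462, 0.00673, 0.00314 and 0.0011 for these lists and adjusted p = 0.812 for each with an estimated correlation. With the floor at the 60th percentile 380 genes were apart in Treg, against 590.

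**Figure D4:**
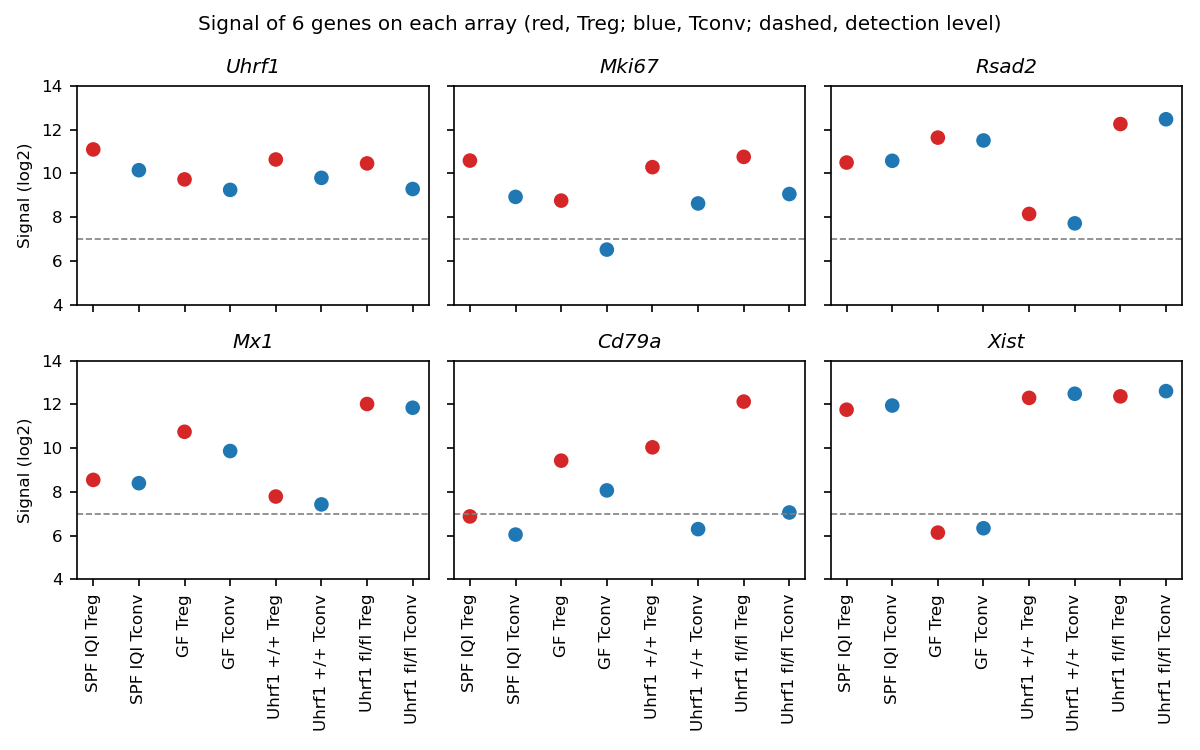
Log2 signal of 6 genes on each of the 8 arrays, 1 point per array, red for Treg and blue for Tconv, with the detection level of 7.0 dashed. Rsad2 reads 12.26 and 12.48 on the Uhrf1 fl/fl arrays and 8.15 and 7.72 on the Uhrf1 +/+ arrays, and Xist reads 6.14 and 6.34 on the GF arrays.

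As a yardstick for differences between sources of wild-type SPF mice, SPF IQI was set against Uhrf1 +/+. This pair differs in strain, source, array quality and Y-linked transcripts together, with Eif2s3y at 11.94 against 2.15 in Treg and 12.39 against 1.33 in Tconv. The sex of the mice thus appears to differ here too. In Treg 1574 genes were higher and 1723 lower in SPF IQI of 10119 measured, and in Tconv 1573 and 1601 of 9774. With the arrays centred on detected genes the balance turned, to 1711 higher and 1478 lower in Treg and 1754 and 1357 in Tconv. Centring sets this balance itself, as the median difference became -0.007 in Treg and 0.008 in Tconv. At 3-fold 921 were higher and 615 lower in Treg, and 950 and 558 in Tconv. At 1.5-fold 2336 were higher and 3037 lower in Treg, and 2262 and 2877 in Tconv. The balance thus depends on the threshold and the centring. Higher in SPF IQI Treg were the pancreatic enzyme genes Ctrb1, at least 225-fold, Cela3b, at least 153-fold, and Cpb1, at least 123-fold, the goblet cell gene Zg16, at least 162-fold, the matrix gene Sparc, at least 151-fold, and Reg2, at least 120-fold. Lower were Mndal, at least 108-fold, the restriction factors Trim12a, at least 57.4-fold, and Trim5, at least 30.0-fold, Tmem14c 38.5-fold, Rab6b at least 31.5-fold and H2-DMb2 27.1-fold. In Tconv Sparc was 179-fold, Ctrb1 at least 149-fold, Reg3b at least 141-fold and Col1a1 at least 130-fold higher, and Mndal at least 107-fold, Trim12a at least 62.3-fold and Ms4a4b 42.9-fold lower, with a log2 difference of -6.13 for Tmem14c. Cdkn1a was 8.07-fold higher in SPF IQI Treg and 9.17-fold in Tconv, Il10 16.4-fold and at least 8.02-fold, and Uhrf1 1.37-fold and 1.28-fold, though Uhrf1 in Tconv differed by -1.72 with the median of both its probe sets. Ctla4 and Foxp3 were 7.58-fold and 2.97-fold higher in SPF IQI Tconv. Centring on detected genes moved the median of all genes by 0.10 in Treg and 0.12 in Tconv. Of the genes measured in both cell types 1146 were higher in both and 1083 lower in both, where independent lists would share 213.6 and 249.7.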

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

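All tests in this part were chosen after the results they bear on had been seen. Of the splits of the 8 arrays into 4 and 4, 8 part all 4 mouse sources as the real one does, too few for a share under 0.05. The real one gave 903 genes of Treg against Tconv and the highest other 0. The others exchange the cell types in part of the sources, which moves the cell type difference into the error. A low count there was therefore fixed in advance and bears neither way on chance. The 24 splits that part only 2 sources, and so keep 4 arrays out of the contrast, gave at most 1. In these too the cell type difference goes into the error. Among the 3 splits without a source term, SPF IQI and GF against the Uhrf1 arrays gave 5073 genes and the other 2 gave 0. That fit counts both cell types of a source as separate replicates. Strain, source, array quality and Y-linked transcripts differ together there, so the count does not tell them apart.

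Interferon-induced genes were higher on both Uhrf1 fl/fl arrays. In Tconv their median of 2.49 (bootstrap 1.77 to 2.98) exceeded the medians of the lists of other cell types that could be compared. These were 0.26 for B cell, 0.31 for CD8 T and NK, and 0.85 for macrophage and dendritic cell genes. The remaining such lists had too few members above the floor on the +/+ array. The comparison argues against a larger share of the compared cell types as the whole cause there. It holds only if their markers rise at least as much as interferon genes. The CD8 genes Cd8a and Cd8b1 did rise, from 7.97 to 9.55 and from 8.31 to 9.44. In Treg the median of 1.82 (bootstrap 1.39 to 2.49) lay below that of plasma cell genes, 2.78 over 4 genes above the floor on the +/+ array, so such cells may contribute. A source with high interferon for a reason other than the genotype stays open. The median level ranged over the SPF IQI, GF and Uhrf1 +/+ sources by 0.76 in Tconv and 1.08 in Treg. The fl/fl differences between the medians of levels were 2.67 and 1.90. GF was highest in both ranges, and SPF IQI and +/+ stood at 9.20 and 9.12 in Tconv and 9.27 and 9.84 in Treg. The genotype is the biological difference the design names, and 1 pair of arrays per cell type cannot separate it from such a source.

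G2 and M phase genes were higher in Uhrf1 fl/fl Treg. Probe sets near the floor are argued against as the cause, since the 19 members above the detection level on both arrays had a median of 0.68, outside random lists (-0.22 to 0.16). Dividing cells of other types could add such transcripts to a fraction with more B cell markers. Tconv, where B cell markers did not differ, had a median of 0.27, just inside random lists (-0.20 to 0.29), which leaves this open. The genotype stays open too.

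Germline genes were higher in Uhrf1 fl/fl Treg. Without the floor, 20 of 24 were higher, with a median of 1.36 outside random lists (-0.44 to 0.49). In Tconv 18 of 24 were higher, with a median of 0.68, also outside random lists (-0.37 to 0.49). But 20 of the 24 lie below the detection level on both Treg arrays, so noise of dim probe sets stays open. Transcripts from B cells may add to the rise in Treg. In Tconv the B cell list did not differ, with a median of 0.26 over 3 genes. Most germline genes lie below the detection level there too, so the rise in Tconv does not settle this. In the Uhrf1 +/+ pair, where Treg had more B cell signal than Tconv, the germline median was -0.57, just below random lists (-0.52 to 0.68), and by the bound first set this would have counted against B cells. That bound was dropped after its value was seen, because 22 of the 24 genes lie at the floor on both +/+ arrays, so this origin and the genotype stay open.

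For 6 of 67 named genes, 1 source's Treg minus Tconv difference stood far from the other 3, where chance gives about 5%. Ctla4 was lowest in SPF IQI, at 0.74 against 2.43 to 2.77. Ahr was lowest in SPF IQI, at 0.87 against 2.22 to 2.33. Socs2 was lowest in SPF IQI, at 1.66 against 3.94 to 4.40. Tk1 was lowest in GF, at 0.22 against 2.0 to 2.30. Mki67 was highest in GF, at 2.24 against 1.65 to 1.70. Icos was highest in Uhrf1 +/+, at 0.99 against 0.46 to 0.53.

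Opposite directions in the cell types appeared for the epithelial list in GF against SPF IQI, with 0.34 in Treg and -0.81 in Tconv. A test of the difference by camera gave adjusted p = 9.22e-07, and adjusted p = 0.254 with an estimated correlation. Tarbp2 differed by -2.06 in Treg and 2.12 in Tconv in the same comparison (limma adjusted p = 0.479 for the difference). Igk-V21 differed by 2.68 in Treg and -1.89 in Tconv between Uhrf1 fl/fl and +/+ (limma adjusted p = 1.0 for the difference).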

How the results depend on the processing

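The fits on 4 arrays alone, the test of differences between cell types, and the counts without other cell types or without genes higher in +/+ Treg, were chosen after the data were seen. The tallies here leave out alternatives whose outcome is fixed: a second quantile normalization, other fold thresholds, leaving out genes higher in +/+ Treg, and, for counts and genes of 1 array against 1, a floor at the 40th percentile. A tally holds each result once per alternative, so its units are pairs of a result with an alternative. Of the pairs for counts, 47 stayed within 1.5 times and 13 did not. Of the pairs for list medians, 631 moved from their main value by no more than the distance from the centre of their random-list range to its end. The other 23 moved further or, lying outside random lists, changed sign. Of the pairs for genes named in comparisons of 1 array with 1, 1565 stayed on the same side of 2-fold and 136 did not. For the 67 genes named for Treg against Tconv, 696 calls stayed and 299 were lost. The lost calls include all 67 on either set of 4 arrays, where 1 residual degree of freedom remains, and 58 without the source term.

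The 903 genes of Treg against Tconv became 577 with the median of all probe sets, 518 without the intensity trend, 39 without the source term (32 higher, 7 lower), 276 to 717 when a source was left out, and 0 on the SPF IQI and GF arrays or the Uhrf1 arrays alone. Fewer arrays account for the last 2, and between-source variation left in the error for the 39. The 13 gene list calls became 0 with an estimated correlation. With the floor at the 60th percentile, which leaves fewer genes measured, counts were 807 and 701 for GF in Treg and Tconv, 241 for GF in both and 380 for fl/fl Treg. A pseudocount gave 897 for GF Treg. By construction a 3-fold threshold gave fewer genes and a 1.5-fold one more: 426 and 3064 for GF Treg, 553 and 2311 for GF Tconv, 243 and 1376 for fl/fl Treg, 79 and 857 for fl/fl Tconv, 1536 and 5373 for SPF IQI against +/+ in Treg, and 1508 and 5139 in Tconv. A change of sign, for any size of difference, was seen 25 times among list medians and 11 times among named genes in comparisons of 1 array with 1, and 17 and 10 of these came with the median of all probe sets. The results described as different that then turned were the sex-linked list in GF Treg (-0.64), the naive list in fl/fl Treg (-0.069) and Grb10 in GF Treg (0.03). Uhrf1, less than 2-fold apart, turned in GF Tconv (-0.90 to 0.26), fl/fl Treg (-0.18 to 0.02) and SPF IQI against +/+ in Tconv (0.36 to -1.72). Its other probe set lies near or below the floor. Other causes were not tested.

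Without lists of other cell types and sex-linked genes, 1339, 1151, 558 and 245 genes were apart in the GF and fl/fl comparisons of Treg and Tconv. This removes only the listed genes, so it does not say how many of the rest come from other cell types. Without genes at least 2-fold higher in +/+ Treg than Tconv, fl/fl Treg kept 394, 362 higher and 32 lower, but +/+ Treg is also the reference there, so this removes falls by construction. A floor at the 40th percentile cannot change counts of 1 array against 1, and a second quantile normalization moved no value, so neither says anything about stability there. No paired analysis was possible because groups hold 1 array each, beyond the mouse source term already in the fit. Signal near the floor limits folds of dim genes.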

Other observations

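Ctrb1, epithelial, immediate early and sex-linked transcripts separated the SPF IQI and GF arrays from the Uhrf1 arrays. Ctrb1, which encodes a pancreatic protease, read 13.70 and 13.10 (log2) on the SPF IQI Treg and Tconv arrays and 13.84 and 10.86 on the GF arrays, and at most 2.25 on the Uhrf1 arrays. The epithelial list had median levels of 8.56 to 9.34 on SPF IQI and GF arrays and lay at the floor, 5.88, on all 4 Uhrf1 arrays. The list for tissues outside the gut wall and lymphoid system did not separate them, with a median at the floor on all arrays but GF Treg (6.31). The immediate early list stood at 11.84 to 12.29 on the former and 10.50 to 10.88 on the latter, with Fos at 12.98 to 13.25 and 9.91 to 11.34. The heat shock gene Hspa1a read 10.67 to 12.04 and 4.59 to 5.60. The Y-linked Eif2s3y and Kdm5d were high on the SPF IQI and GF arrays, at 11.94 to 12.71 and 10.06 to 10.47, and low on the Uhrf1 arrays, while Xist was high on the SPF IQI arrays too, so both kinds of sex-linked transcript stood side by side there. Cd8a, a member of the CD8 T and NK list, read 10.31 and 7.97 on the Uhrf1 +/+ Treg and Tconv arrays and 11.96 and 9.55 on the fl/fl arrays. It read 7.90 and 7.78 on the SPF IQI arrays and 8.73 and 6.38 on the GF arrays, above the detection level of 7.0 on all but GF Tconv. Cd8b1 of the same list read 8.31 to 10.60 on the Uhrf1 arrays and 4.67 to 5.87 on the SPF IQI and GF arrays, below the floor. Cd8a alone therefore does not show CD8 T cells on the SPF IQI and GF arrays.

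The germ-free and Uhrf1 fl/fl comparisons share no array. In Treg 59 genes were higher in both, where independent lists would share 10.1, and 11 of the 59 stand in the interferon list and 5 in the B cell list. Another 69 were lower in GF and higher in fl/fl, where 23.4 would be shared, 3 of them G2 and M phase genes. Lower in both were 24 against 6.5, and 6 were higher in GF and lower in fl/fl against 2.8. In Tconv 21 were higher in both against 3.0, with 12 interferon genes, and 37 were lower in GF and higher in fl/fl against 4.3, with 5 Th1 genes. Lower in both were 18 against 1.9, and 2 were higher in GF and lower in fl/fl against 1.3. That last direction holds too few genes to tell from independent lists. The other directions held more shared genes than independent lists would in both cell types, without a test. Interferon genes had median levels of 9.27 and 9.20 in SPF IQI Treg and Tconv, 10.35 and 9.89 in GF, 9.84 and 9.12 in Uhrf1 +/+, and 11.74 and 11.79 in Uhrf1 fl/fl.

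One hypothesis was tested for the genes changed the same way in both fl/fl arrays: variants carried along with the altered Uhrf1 allele may account for those next to it. The test was set before its result was seen. Of the 200 measured genes nearest to Uhrf1 in chromosome order, 4 were such genes, H2-Q10, Gm9706, Xdh and Eif2ak2, named after their values were seen. Over 4824 windows of 200 genes the median was 2 and 95% held at most 6, so the count lies between the bounds and the hypothesis stays open.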
